A study of Mus musculus with 4 samples.

How the data were processed

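The series holds 2 m6A-eCLIP libraries and 2 input RNA libraries from mouse embryonic fibroblasts expressing the oncogenes E1A and HRasV12. In m6A-eCLIP an antibody against N6-methyladenosine is crosslinked to mRNA and the bound fragments are sequenced, so that a pile of fragments over the input marks a methylated stretch. One condition carried control shRNA (named for luciferase in the sample title) and the other an shRNA against Mettl3, the catalytic subunit of the m6A methyltransferase. Cells of both conditions received doxorubicin, a DNA-damaging drug, at 0.2 µg/ml for 6 h. Each condition had 1 library of each kind, so groups follow the labels and no replicate check was possible.

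UMI-tools 0.5.1 and cutadapt 2.7 were used on the reads and the build was mm10, per the submitters' processing notes. The aligner, peak caller and statistical test are not given in the sources used here. The authors deposited 1 list of peaks over input for each m6A-eCLIP library and 1 list comparing the control library with the Mettl3-knockdown library. In the lists over input the authors gave a log2 fold over input and a −log10 p-value per peak. The −log10 values are limited to 400 in the deposited lists. In the comparison list the authors gave a log2 fold change difference, control over Mettl3 knockdown, and a p-value per peak. It holds only peaks higher in the control, so it says nothing of peaks higher after the knockdown. All folds and p-values per peak are the authors' own and were used only to describe, rank and filter peaks within a list. The name of the deposited comparison list speaks of a log2 fold change of 1, while its smallest value was 0.50, so the list was used as it stands and a minimum of 1 was added as an alternative. The difference was checked against the lists over input: 5 peaks had identical ends in all 3 lists, and in all 5 the difference equalled the control minus the knockdown log2 fold over input within 1e-06. The authors' region and gene annotation was used for every peak. Of 6076 Ensembl gene identifiers in the lists, 6072 matched the name table. Neighbouring peaks of a list often shared a border (7410 pairs in the control list) and none overlapped, so starts were read as 0-based and are printed 1-based.

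Read depth of the libraries was not analysed here, and neither input library was used other than through the authors' folds. Peak sets were compared with bedtools 2.31.1, with a peak counted as shared when at least 1 base overlapped on the same strand. Shares carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover counting error only and treat peaks as independent although many adjoin. Tables were handled with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9. Before the data were examined, 15 gene lists, the comparisons, their alternatives and the rule for named genes were fixed. For each list, the share of members with a control peak that also held a peak higher in the control was set against 10000 random lists of the same size. Random lists were drawn from the genes with a control peak and matched on control peaks per gene (1, 2, 3 to 4, 5 or more). The percentile describes these libraries and is no test of the conditions. Lists with fewer than 3 members carrying a control peak received no percentile. The procedure was tested on simulated data over the 4765 genes with a control peak. With no enrichment, 1.5% of 200 lists of 25 genes lay above the 97.5 percentile and 5% below the 2.5 percentile, and with a share raised by 40 percentage points 100% lay above. Smaller excesses and smaller lists were not simulated, so a place within the random range does not exclude an excess.

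Named genes were Mettl3, then the 10 genes with the largest log2 difference among peaks with −log10 p of at least 3, and the 5 genes with most peaks higher in the control. Members of each gene list with such a peak followed, ranked by difference, up to 6 for p53 targets and 4 for other lists. The 5 genes with the largest fold in each list over input completed the rule, and some genes that it names are not reported here. Alternatives covered stricter thresholds, merged peaks, other definitions of overlap, weighting by peak length, and other backgrounds for the gene lists. The comparison of DRACH motifs, the sequence context of m6A, was not run because no genome sequence was used here.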

Results

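m6A-eCLIP was used to map N6-methyladenosine in mRNA of mouse embryonic fibroblasts expressing E1A and HRasV12, after 6 h of doxorubicin at 0.2 µg/ml. The question was which m6A sites depend on Mettl3, the m6A methyltransferase, during DNA damage. The data comprised 1 control library, 1 Mettl3-knockdown library and an input RNA library for each. The authors listed 15439 peaks over input in 4765 genes for the control and 15417 peaks in 4651 genes for the knockdown. Median peak lengths were 119 and 114 bases. Folds over input of the listed peaks were somewhat larger in the knockdown list, with a median log2 fold of 3.69 in the control and 3.83 in the knockdown. A log2 fold of at least 4, a setting chosen after seeing the data, was reached by 5048 control and 6376 knockdown peaks. All listed peaks had a log2 fold over input above 3, and 55.9% of control peaks and 57.4% of knockdown peaks stood at the upper limit of the deposited −log10 p. There was 1 library per condition, so no difference below has a replicate check, and intervals cover counting error only. Mettl3 itself had 0 peaks in each of the 3 lists. Since peaks do not give transcript levels, the extent of the knockdown was not analysed here.

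The first comparison asked how far the peaks of both libraries coincided. A knockdown peak overlapped 12516 control peaks, or 81.1% (95% interval 80.4 to 81.7). A control peak overlapped 12911 knockdown peaks, or 83.7% (83.2 to 84.3). At the level of genes, 3947 carried peaks in both lists, 818 only in the control list and 704 only in the knockdown list. The largest control folds over input lay in Arhgap29 (log2 6.75), Trim36 (6.64), the calcium sensor Stim2 (6.58), the N-terminal acetyltransferase Naa30 (6.55) and Trim62 (6.47). In the knockdown list they lay in the neural transcription factor Pou3f2 (8.39), Irs4, an insulin receptor substrate (8.13), the Notch target Hey1 (8.04) and Qsox2 (7.33). The linear folds of Trim36, Trim62, Pou3f2, Irs4 and Hey1 were whole multiples, within 0.0001, of a step shared by many peaks of their list (1.17 in the control, 0.986 in the knockdown), as were those of 8.67% of control and 10.1% of knockdown peaks. Peaks found in both libraries were the more strongly supported ones. Of control peaks, 63.3% of those overlapped by a knockdown peak stood at the upper limit of −log10 p, against 24.3% of the others, and for knockdown peaks these shares were 64.8% and 19.1%. Among peaks with a log2 fold of at least 4, a setting chosen after seeing the data, 93.3% of control peaks were overlapped in the knockdown list.

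Coding sequence held most peaks of both lists over input. It took 57.0% of control peaks (56.2 to 57.8) and 60.5% of knockdown peaks (59.8 to 61.3). The 3' UTR took 30.9% of control peaks (30.1 to 31.6) and 27.3% of knockdown peaks (26.6 to 28.1). The 5' UTR took 1.79% (1.58 to 2.01) and 2.39% (2.16 to 2.65). Introns held 5.91% and 5.22%. The regions parted further among unshared peaks: the 3' UTR took 32.1% of the 2923 control-only peaks (30.4 to 33.8) and 17.1% of the 2506 knockdown-only peaks (15.7 to 18.7). The 5' UTR took 1.88% of the former (1.42 to 2.44) and 4.91% of the latter (4.10 to 5.83). Of knockdown peaks, 89.8% in the 3' UTR were matched in the control, against 84.5% in coding sequence and 66.7% in the 5' UTR. Of control peaks, 80.3% in the 3' UTR, 84.9% in coding sequence and 80.1% in the 5' UTR were matched in the knockdown, so the order of the regions differed with the direction.

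The second comparison was the authors' own search for Mettl3-dependent m6A. The authors' deposited table held 1851 peaks in 1220 genes that were higher in the control than after Mettl3 knockdown. Their median log2 difference in the authors' deposited table was 0.76, a 1.70-fold difference, with quartiles of 0.63 and 0.97. Of these peaks, 1094, or 59.1% (56.8 to 61.4), lay in the 3' UTR and 39.8% (37.5 to 42.0) in coding sequence, in the authors' deposited table. The 5' UTR and introns held 0.324% and 0.378% of them. At −log10 p of at least 5, a setting chosen after seeing the data, the 3' UTR share was 75.7% and the coding-sequence share 23.9% in the authors' deposited table, and weighted by length they were 50.2% and 48.7%. Measured on the control list, a peak higher in the control overlapped 5.37% of 3' UTR peaks (4.75 to 6.05) and 1.85% of coding-sequence peaks (1.58 to 2.16). A log2 difference of 1 was reached by 416 peaks in the authors' deposited table, while 22 reached 2 and 642 had a p of at most 0.001. Most of these sites were not listed as peaks over input: 1426 of the 1851, or 77.0% (75.1 to 78.9), overlapped neither list over input, and 412 overlapped a control peak. Both lists hold only peaks with a log2 fold over input above 3, so an unlisted site may still be enriched less strongly. The same limit holds wherever a gene or site below has no peak over input.

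**Figure D1:**
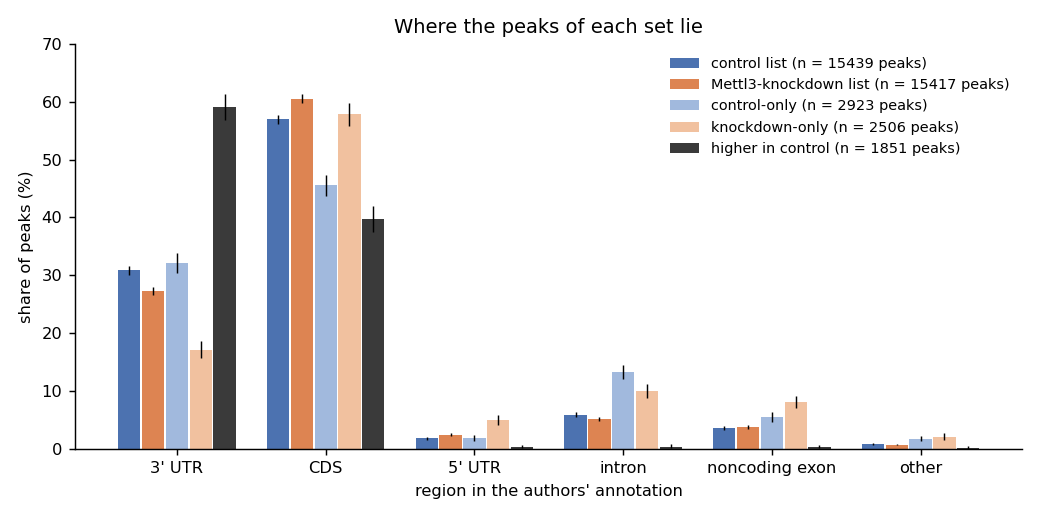
Share of peaks (%) by the authors' annotated region for the control list, the Mettl3-knockdown list, the peaks of each found in that list alone, and the peaks deposited as higher in the control. Bars are shares and error bars exact 95% intervals over peaks, and the 3' UTR share is 27.3% in the knockdown list and 59.1% among the peaks higher in the control.

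The largest differences among peaks with −log10 p of at least 3 lay in genes of varied function. In the authors' deposited table, Qser1 led with a log2 difference of 3.69 (p = 4.17e-05) in its coding sequence, at chromosome 2, 104758478 to 104758528 of mm10, on the minus strand. The histone methyltransferase gene Setd1a followed in the authors' deposited table with 2.42 (p = 4.73e-10), also in coding sequence, at chromosome 7, 127797075 to 127797086. Tnrc6c, a component of microRNA-guided silencing, had 2.29 (p = 4.66e-04) and the centriolar gene Lrrcc1 2.21 (p = 3.29e-05) in the authors' deposited table, both in coding sequence. Between 1.84 and 1.63 in the authors' deposited table came Mob1b, a Hippo pathway gene, Tmem167b, Eef1aknmt, the glycosyltransferase locus Galnt2|Galnt2l, the MAP kinase effector Rps6ka3 and the RNA exosome gene Exosc1. Of these 10 genes, 4 had no peak in either list over input (Lrrcc1, Mob1b, Tmem167b and Eef1aknmt). Of the 10 peaks themselves, only those of Tnrc6c and Rps6ka3 overlapped a control peak, and none overlapped a knockdown peak. The peaks of Qser1 and Setd1a thus lay outside the peaks over input of these genes.

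The translation elongation factor gene Eef2 had 14 peaks in the authors' deposited table, all in the 3' UTR within chromosome 10, 81182130 to 81182322, with log2 differences of 0.51 to 0.70 and p from 6.00e-47 to 1.60e-19. None of these overlapped a peak over input, and Eef2 had 0 peaks in either list over input. The protease gene Ctsb and the matricellular gene Ccn1 each had 13 in the authors' deposited table, all in the 3' UTR, at 0.53 to 0.73 and 0.52 to 0.68. Ccn2, a YAP target, had 11 in the authors' deposited table at 0.78 to 1.29, and the nucleolin gene Ncl 11 at 0.50 to 0.81. Adjoining peaks of a gene are pieces of the same stretch, and merging them, a setting chosen after seeing the data, left 1460 from the 1851.

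**Figure D2:**
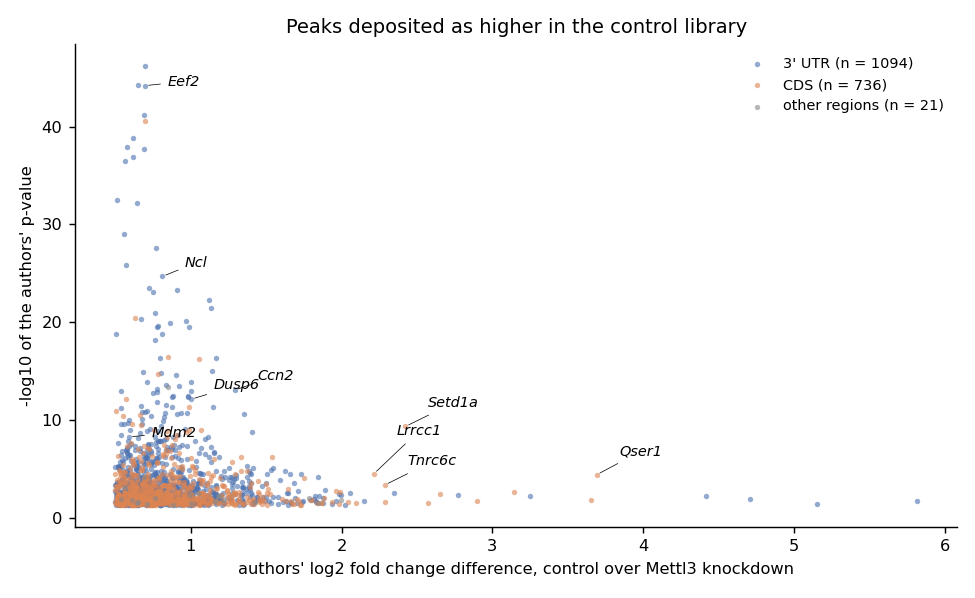
The log2 fold change difference, control over Mettl3 knockdown (x axis), and −log10 of the p-value (y axis) of the 1851 peaks in the authors' deposited table, 1 point per peak, coloured by region. Most points lie near the median of 0.76, with Eef2 and Ncl high on the y axis at modest differences and Qser1 at 3.69.

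Mdm2, the ubiquitin ligase that restrains p53 and is itself a p53 target, differed between the lists along its 3' end. Its peaks were adjoining pieces, 22 in the control list and 32 in the knockdown list, and joining them, a setting chosen after seeing the data, left 1 stretch in coding sequence and 1 in the 3' UTR in each list. The 3' UTR stretch spanned 95 bases in the control list (117690086 to 117690180) and 9 bases in the knockdown list (117690130 to 117690138). Both lists hold only peaks with a log2 fold over input above 3. The 3' UTR pieces of the control list stood at 3.30 to 3.60, not far above that limit. A modest fall could take such pieces under it, so the shorter stretch need not mean a lost signal. The control piece at 117690086 to 117690104 stood at 3.30 with a listed difference of 0.54, and that at 117690156 to 117690180 at 3.44 with 0.54. Read as control minus knockdown, these differences put the knockdown fold a little under the limit, still well over input. The piece at 117690123 to 117690131, at 3.60 with 0.52, would stay above it. The coding-sequence stretch spanned 93 bases in the control list and 140 in the knockdown list. The authors' deposited table held 7 peaks higher in the control, all in the 3' UTR between 117690049 and 117690209 of chromosome 10 (mm10, minus strand). Their log2 differences in the authors' deposited table ran from 0.52 to 0.59, with p from 1.11e-13 to 2.31e-08. Of these 7 peaks, 5 overlapped a control peak and 1 a knockdown peak. Coding-sequence peaks of Mdm2 reached 117690385 in both lists over input, with a largest log2 fold over input of 3.91 in the control list and 4.33 in the knockdown list. The comparison list holds only peaks higher in the control, so it gives no difference or p for these coding-sequence peaks.

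**Figure D3:**
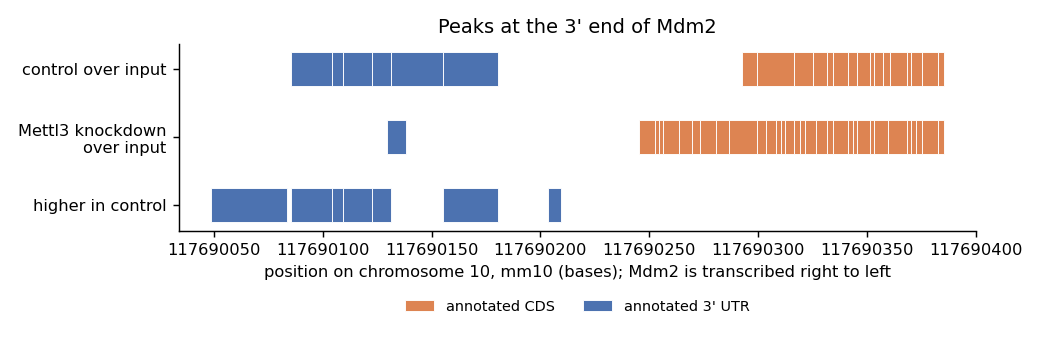
Peaks at the 3' end of Mdm2 on chromosome 10 (x axis, mm10 position in bases) in the control list, the Mettl3-knockdown list and the list of peaks higher in the control, coloured by annotated region. Adjoining pieces form 1 stretch of 95 bases in the 3' UTR of the control list and 1 of 9 bases in that of the knockdown list, and all 7 peaks higher in the control lie in the 3' UTR. Both lists over input hold only peaks with a log2 fold above 3, so a missing piece need not mean a lost signal.

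Genes of the p53 response were tested as a list. Of 63 p53 targets, 30 had a control peak and 25 a knockdown peak; 5 had one only in the control and 0 only in the knockdown. Those 5 were Eda2r, Sesn1, Trp53cor1, Trp53inp1 and Trp73, named after their values were seen. A peak higher in the control lay in 13 p53 targets, 9 of them among the 30, or 30% (14.7 to 49.4). Random matched lists averaged 14.0% with a central range of 3.33% to 26.7%, and the p53 targets stood at percentile 99.0. The lists were matched on control peaks per gene and not on expression or read coverage. Whether higher coverage of the p53 targets raised their share was not tested. Besides Mdm2, the log2 differences in the authors' deposited table were 0.92 for the ubiquitin ligase gene Fbxw7 (p = 0.0456), 0.81 for the thiamine transporter Slc19a2 and 0.80 for the polymerase Polk. They were 0.77 for Psrc1 (p = 1.38e-12) and 0.68 for the exonuclease Aen in the authors' deposited table. Slc19a2 and Psrc1 had no control peak and so were not among the 30. Aen had 6 such peaks, all in coding sequence. There each list over input held 1 joined stretch, of 177 bases in the control and 138 in the knockdown. Over the whole gene there were 4 joined stretches in the knockdown list and 3 in the control list, the others lying in the 3' UTR. The result depended on how dependence was defined: counting genes with a control peak and no knockdown peak gave percentile 83.9. With a log2 difference of at least 2, where only 22 genes of the whole list remained, none of the 30 qualified, which gave percentile 44.6. So few genes cannot decide for or against the p53 targets. Every list with 0 qualifying genes stood between 44.6 and 48.9 at that setting.

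Regulators of p53 and genes of DNA repair lay within the random range. Among 31 p53 regulators, 3 of the 18 with a control peak also had a peak higher in the control (16.7%, percentile 67.1). In the authors' deposited table the deacetylase Sirt1 had a log2 difference of 1.22, Csnk1a1 0.80 and the histone methyltransferase Kmt5a 0.76. Kmt5a had no control peak and so was not among the 18, and Mdm2 was the other member of the 3. Among 66 DNA damage and repair genes the share was 3 of 26 (11.5%, percentile 49.1), and 7 of the 10 with a peak higher in the control had no peak over input. The excision repair gene Xpa had 1.29 (p = 0.00353), the checkpoint mediator Clspn 0.97 (p = 2.31e-04), Fanci 0.95 (p = 0.0112) and Rif1 0.91 (p = 0.0361) in the authors' deposited table. Of these only Rif1 had a control peak and so was among the 26.

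The m6A machinery and apoptosis genes each held 5 genes with a peak higher in the control. For the 26 genes of the m6A machinery the share was 4 of 12 (33.3%, 9.92 to 65.1, percentile 94.0). Wtap, the adaptor of the methyltransferase complex, had 3 coding-sequence peaks of up to 1.01 in the authors' deposited table. The m6A reader Ythdc1 had 0.80 (p = 0.0269), the RNA-binding protein gene Elavl1 0.76 and the reader Ythdf1 0.67 in the authors' deposited table. Elavl1 had no control peak and so was not among the 12. The other member of the 4 was Ythdf2 (0.63), which lies outside the rule for named genes. For 37 apoptosis genes the share was 2 of 14 (14.3%, percentile 61.1). Mcl1, an anti-apoptotic member of the Bcl2 family, had 7 control peaks in 2 joined stretches and 0 knockdown peaks, with 3 adjoining peaks of up to 0.71 (p = 9.33e-04) in the 3' UTR in the authors' deposited table. Its control stretch in coding sequence held no peak higher in the control, so the absence of knockdown peaks there goes with no listed difference. The mitochondrial protease Htra2 had 1.41, the kinase Ripk1 1.29 and Casp8 0.72 in the authors' deposited table. Htra2 and Casp8 had no control peak and so were not among the 14, of which Mcl1 and Ripk1 were the 2 counted.

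Cell-cycle genes rarely carried peaks over input. Only 7 of 55 had a control peak, yet 11 had a peak higher in the control, and 9 of those 11 had no peak in either list over input. The pocket protein gene Rbl2 had 1.27, the mitotic kinase Aurka 0.99, E2f8 0.86 and the replication licensing gene Cdc6 0.86 in the authors' deposited table. The share among those with a control peak was 2 of 7 (percentile 83.6). Of the immediate early genes 25 of 33 had a control peak and 1 of those 25, or 4% (0.101 to 20.4), had a peak higher in the control (percentile 8.25), which is within the random range. It was Klf6, with 1.26 in the authors' deposited table, and Fosl1, which had no control peak, had 0.59.

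Matrix and fibroblast genes stood at percentile 97.9, with 4 of 11 (36.4%, 10.9 to 69.2), a share equal to the upper end of the random range. Among the 4, Fbn1, encoding fibrillin, had 1.40 and Ccn2 1.29 in the authors' deposited table. The collagen gene Col6a2 had 1.08 (p = 0.0265) and Loxl2 0.90 (p = 0.00224) in the authors' deposited table, both without a control peak and so outside the 11. None of the 11 lacked a knockdown peak, so counting genes with a control peak and no knockdown peak gave percentile 7.18. At a log2 difference of at least 2 none of the 11 qualified and the percentile was 48.3, which again decides nothing. With a background of genes with a peak in any list, a setting chosen after seeing the data, the percentile was 97.0. RAS and MAP kinase genes had 5 of 21 (23.8%, percentile 91.3), with 1.66 for Rps6ka3, 1.01 for Rasa1 (p = 0.0418) and 1.00 for the ERK phosphatase Dusp6 in the authors' deposited table. Chromatin modifiers had 8 of 38 (21.1%, percentile 83.0), led after Setd1a by the demethylases Kdm3b at 1.39 and Kdm2a at 1.19 in the authors' deposited table. Bptf, which had no control peak and so was not among the 38, had 1.16 (p = 0.0220) in the authors' deposited table. Of the 11 lists with a percentile, the p53 targets alone had a share above the central 95% range of their random lists. The share of matrix and fibroblast genes equalled the upper end of their range. By percentile, 2 lists passed the upper limit of the central 95%, the p53 targets and the matrix and fibroblast genes. The percentile was the rule for calls under other settings, and no adjustment was made for the number of lists.

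Ribosomal and respiratory chain genes were almost without peaks. Of 46 ribosomal protein genes, 0 had a control peak and 1, Rpl30, named after its values were seen, had a knockdown peak. None of 40 oxidative phosphorylation genes had a peak in any list. Of 19 nuclear long noncoding RNAs, 7 had a control peak, and Neat1 alone had a peak higher in the control (0.85, p = 4.10e-14, in the authors' deposited table; percentile 49.4). Markers of other cell types were scarce. Of 20 haematopoietic markers 1 had a control peak and 2 a knockdown peak, and of 25 epithelial, endothelial and neural markers 1 and 3 did. Nes, a neural progenitor marker, had a peak higher in the control at 0.64 in the authors' deposited table.

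**Figure D4:**
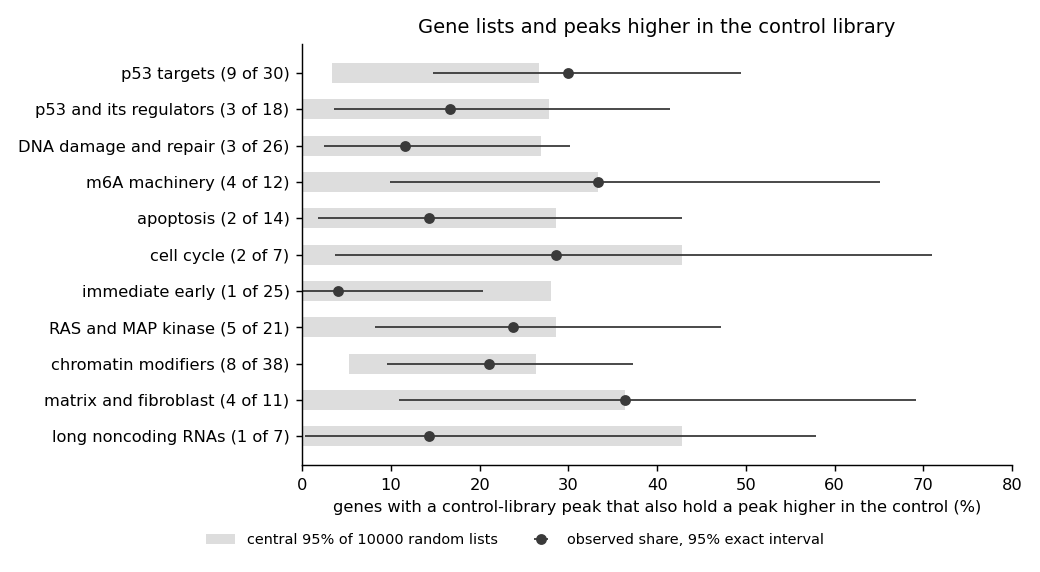
Share (%) of genes with a control peak that also held a peak higher in the control, for the 11 gene lists with a percentile. Points are observed shares with exact 95% intervals and grey bars the central 95% of 10000 random lists, and the p53 targets at 30% lie above their random range of 3.33% to 26.7%.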

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

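Over 46 results and 164 alternatives, 101 values kept their direction and side of the threshold or stayed within their interval or 1.5 times the count, 58 moved, 2 lost their call and 3 reversed. Settings chosen after seeing the data were the log2 minimum of 4, the minimum of 1 in the comparison list, the removal of peaks on the common step, merging for overlaps and in the comparison list, −log10 p of at least 5 for regions, and the background of genes with a peak in any list. Merging touching peaks left 8029 control and 7827 knockdown peaks, and a log2 fold of at least 4 left 5048 and 6376. The control peaks overlapped in the knockdown list were 77.6% with overlap of at least 50% of the peak, 84.0% within 50 bases, 73.2% merged, 93.3% at log2 of at least 4 and 83.6% without peaks on the common step. For knockdown peaks overlapped in the control these were 81.0%, 86.1%, 75.7%, 92.4% and 87.1%. Weighting by length moved the 3' UTR and coding-sequence shares to 50.2% and 48.7% of the peaks higher in the control. It moved them to 25.4% and 62.0% of control peaks (introns 6.71%) and to 22.8% and 64.9% of knockdown peaks (5' UTR 1.90%, introns 5.84%). At −log10 p of at least 5 the peaks higher in the control were 75.7% 3' UTR, 23.9% coding sequence and 0.373% noncoding exon, with 0 in the 5' UTR, introns and the remaining category. At that setting control peaks were 57.9% coding sequence, 5.03% intron and 3.32% noncoding exon, and knockdown peaks 61.4%, 4.43% and 3.36%. In each of these settings the 3' UTR share was larger among peaks higher in the control than in either list over input. In the authors' deposited table, peaks higher in the control and their genes numbered 416 and 366 at log2 of at least 1, 22 and 22 at 2, 8 and 8 at 3, 268 and 151 at −log10 p of at least 5, and 412 and 268 where they overlapped a control peak. At log2 of at least 2 the share with such a peak was 0 in the lists of p53 targets, p53 regulators, DNA damage and repair, m6A machinery, apoptosis, cell cycle, immediate early, RAS and MAP kinase, matrix and fibroblast genes and long noncoding RNAs, and 2.63% in chromatin modifiers. Taking genes with a control peak and no knockdown peak gave shares of 0 for the m6A machinery and for matrix and fibroblast genes and 7.89% for chromatin modifiers. The percentile of p53 targets was 44.6 at log2 of at least 2, counted as reversed. Only 22 genes of the whole list remained there and none was a p53 target, so that value is no contrary evidence. The percentile fell to 83.9 for genes with no knockdown peak, where the cause was not tested. The percentile of matrix and fibroblast genes was 48.3 and 7.18 under the same settings, both counted as reversed. Both values follow from there being 0 such genes among the 11. With the background of genes with a peak in any list it was 97.0, which counted as a lost call. The cause of that change was not tested. A minimum of log2 3 with −log10 p of 3, or of log2 2, removed no peak from the lists over input and so says nothing of their stability, and in the comparison list the former left too few peaks for region shares. The DRACH comparison and its alternatives were not run, as no genome was used here. No paired analysis was possible because each group had 1 library and no result came from a test between groups. Read depth was not analysed here, so its limits on these results are unknown.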

Other observations

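The tests of random splits, threshold, transcript abundance, 3' coverage (with its restriction to 3' UTR and coding sequence) and markers of other cells in this part were chosen only after the results were seen, and so was the search for a common step, although the outcome that would bear on the families was set down before that test was run.

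Genes of developmental transcription factor families (18 families by name, such as Hox, forkhead, Sox and POU, listed after the data were seen) were more frequent among genes with a peak in the knockdown list alone than among those with a peak in the control list alone. They made up 23 of 704 such genes, or 3.27% (2.08 to 4.86), against 7 of 818, or 0.856% (0.345 to 1.76), of genes with a peak in the control list alone. Random splits of the same genes gave 13.9 on average with a central range of 9 to 19, which put 23 at percentile 99.93, a description only, since the families were picked on these data. Among genes with peaks in both lists the share was 1.85% (73 of 3947, 1.45 to 2.32), an interval that meets that of the knockdown-only genes, and 2 of those 73 had a peak higher in the control. Pou3f2 (log2 fold over input 8.39), Foxd3 (7.01), Hoxc10 (5.79) and Sox2 (5.34), the last 3 named after their values were seen, had knockdown peaks and no control peak, and these linear folds were all whole multiples of the common step described in the next paragraph. The Y chromosome held 0 control peaks and 1 knockdown peak, in Uba1y at 826773 to 826881 (log2 fold over input 4.50, likewise a multiple of the step), also named after its values were seen.

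Whether the larger count of these families in the knockdown list could come from folds set by an input at its minimum was not decided. Linear folds of 8.67% of control peaks and 10.1% of knockdown peaks were whole multiples, within 0.0001, of a common step of 1.17 and 0.986, and such peaks made up 21.0% and 28.5% of unshared peaks. Without them the families made up 9 of 416 knockdown-only genes, or 2.16% (0.994 to 4.07), and 5 of 616 control-only genes, or 0.812% (0.264 to 1.88), at percentile 96.02, at the upper end of the random range of 2 to 9. That was the outcome set down beforehand for this explanation, and the removal took 14 of the 23 family genes against 288 of the 704 knockdown-only genes, while the ratio of the shares went from 3.82 to 2.67 and the count over its random mean from 1.65 to 1.59; a smaller excess and smaller numbers were not separated, and the reading was changed to undecided after the values were seen. Cells of another type stay open too, with 5 of 45 markers of other cells carrying a knockdown peak and 2 a control peak, too few to decide, and an effect of the Mettl3 knockdown itself stays open and was not tested.

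The 3' UTR share of 59.1% among peaks higher in the control, against 30.9% of control peaks, was weighed against 3 technical explanations. Weak sites that miss the threshold over input are argued against as the whole cause, because peaks higher in the control that did overlap a control peak had a 3' UTR share of 59.5% (54.5 to 64.2). A difference in abundance of whole transcripts was not decided. In the 5 peaks checked, the log2 difference was one between folds over input, which already sets each signal against input RNA. Whether that removed effects of abundance across the list was not tested. It was examined in 89 genes with control peaks in both regions and at least 1 of them overlapped by a peak higher in the control. There 36.5% of 3' UTR peaks (31.1 to 42.3) and 15.3% of coding-sequence peaks (11.7 to 19.6) overlapped a peak higher in the control. Read coverage, which bears on whether a difference is called, was not matched between the regions. Adjoining pieces were also counted as separate peaks. Lower coverage of 3' ends in the knockdown library remains possible: in genes with no peak higher in the control 28.7% of control-only peaks (26.9 to 30.5) and 16.8% of knockdown-only peaks lay in the 3' UTR, 11.9 percentage points apart (8.45 to 15.2), although shared control peaks, at 29.9% (29.0 to 30.8), were no lower than control-only ones. Of peaks in the 3' UTR or coding sequence alone, the 3' UTR took 38.5% of control-only (36.2 to 40.8), 33.3% of shared control (32.4 to 34.3) and 22.6% of knockdown-only peaks (20.6 to 24.6), and since a loss of m6A in the 3' UTR after Mettl3 knockdown would give the same order, these data leave both open.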
